A study of Mus musculus with 9 samples.

How the data were processed

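RNA was extracted from the livers of 9 mice, 3 per group and 1 library per mouse, per the series' design text. Poly(A)-enriched libraries were read in pairs on a DNBSEQ-T7 instrument, per the labels' protocols. The groups were mice on chow, mice with metabolic dysfunction-associated steatohepatitis (MASH) induced by the GAN diet and given an adeno-associated virus (AAV) control vector, and such mice given an AAV carrying sIL1RAP, the soluble form of the interleukin-1 receptor accessory protein. These groups are called chow, GAN vector and sIL1RAP. The first group's titles spell the diet in a variant form, and the series' design text names it chow.

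The deposited table of read counts held whole numbers for 55487 Ensembl genes, with positions on GRCm38.p6 per the file headers. The submitters' processing notes name fastp, HTSeq and the build mm10. Their versions, the aligner, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The deposited FPKM equalled the count divided by exon length and by the library total for all but 2 genes, within a relative tolerance of 1e-06, and the deposited TPM equalled the FPKM rescaled to a fixed sum per library for every gene. Counts were the basis of all main results, TPM entered only as an alternative, and FPKM served only for this check. The count table held 0 rows without a gene name, and 30263 genes had no read in any library.

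Library totals ran from 17216285 to 26536396 counts. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Libraries were scaled with TMM factors, genes were kept by filterByExpr at its default settings (13522 genes, holding 99.9% of the counts of each library), and all 9 libraries entered a single edgeR fit (4.0.16, R 4.3.3) with a mean per group and no further covariate. Differences were tested with edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM values from edgeR on TMM-scaled libraries, as mean ± SD over 3 libraries. For a gene with 1 to 3 reads in a whole group, the ratio of reads is given with its exact 95% binomial interval. For a gene with 0 reads in a group, the fold is taken against a floor of 3 reads over the group, with the lower limit of the exact 95% interval beside it.

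The 40 gene lists were fixed before the data were examined. The 37 lists with at least 5 genes tested went through limma's camera (3.58.1) with a preset correlation of 0.01 between genes, with camera's estimated correlation and fry beside it, adjusted over the lists. The lists of pancreas, skeletal muscle and mesothelial transcripts had fewer genes tested. The genes named in the text follow a rule fixed at the same time: Il1rap; for GAN vector against chow and for sIL1RAP against GAN vector, the 10 largest rises and 10 largest falls among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups' libraries, leaving out predicted genes, pseudogenes and antigen receptor segments; up to 4 members past the threshold from each list, by smallest adjusted p; members of the NF-kB target and IL-1 family lists; and the 10 genes past the threshold in both comparisons in opposite directions with the largest smaller change. Genes named outside this rule are said to be so.

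The procedure was tested on simulated counts for the 13522 genes, drawn from these libraries' means, sizes and dispersions, with known folds put on some genes. In the simulated comparison of GAN vector with chow, 47.8% of 1.5-fold, 79.1% of 2-fold and 95.5% of 4-fold changes were recovered, with 4 false calls. In that of sIL1RAP with GAN vector the shares were 40.3%, 74.6% and 97.0%, with 9 false calls. For the overlap of the comparisons that share the GAN vector libraries, 20 simulated data sets had no group difference, and another 20 kept the diet difference with sIL1RAP set equal to GAN vector.

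The alternatives fixed together with the lists were RLE and upper quartile scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 (1.42.0), limma-voom, only the 6 libraries compared, the replicate number as a block, each library left out in turn, an added 2-fold threshold, and limma on log2(TPM + 1) or log2(TPM + 0.1) for genes with a mean TPM of at least 0.5 or without that filter. Alternatives added after the data were seen were the removal of each library's trend with transcript length and GC content, the summing of chow replicates 1 and 2, and the removal of 3 genes tied to ribosomal RNA. Transcript length and GC content came from GENCODE M21 on GRCm38, the longest transcript of each gene, and 99.9% of the genes tested had a value.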

Results

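Liver RNA was counted per gene in 9 mice, 3 each on chow, on the GAN diet with a control vector, and on the GAN diet with AAV-sIL1RAP. The totals were 18072022, 18871162 and 20074147 counts in chow replicates 1 to 3. They were 18469670, 19299850 and 17216285 in the GAN vector replicates, and 26536396, 24554133 and 18327028 in the sIL1RAP replicates. Il1rap, the gene of the interleukin-1 receptor accessory protein (ENSMUSG00000022514, chromosome 16, 26581704 to 26730117, plus strand, GRCm38.p6), stood at 232 ± 4.90 CPM in chow, 238 ± 5.52 in GAN vector and 1097 ± 11.9 in sIL1RAP libraries (SD, n = 3 each). It was 4.60-fold higher in sIL1RAP than in GAN vector, in 3 of 3 libraries (log2 fold change 2.20, SE 0.06, adjusted p = 1.75e-08). Between GAN vector and chow it did not pass the test (log2 fold change 0.04, SE 0.06, adjusted p = 0.674). Counts per gene cannot separate reads of the transgene from those of the mouse's own gene.

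Libraries of a group lay close together, with the exception of chow replicate 3. The 7 pairs of libraries of a group without chow replicate 3 correlated across genes at r = 0.993 to 0.994 on log2 CPM, genes not being independent replicates. A gene differed within these pairs by a median of 1.04- to 1.07-fold, against 1.18- to 1.25-fold between libraries of different groups without chow replicate 3 and 1.13- to 1.17-fold between chow replicate 3 and the GAN libraries. Chow replicate 3 correlated with chow replicates 1 and 2 at 0.966, with the GAN vector libraries at a mean of 0.985 and with the sIL1RAP libraries at a mean of 0.974. The biological coefficient of variation was 12.8% over all 9 libraries and 5.73% without chow replicate 3. In the 7 close pairs the median chi-square of a gene's counts ran from 0.529, for chow replicates 1 and 2, to 2.15, where counting error alone gives 0.455. Each library came from 1 mouse per the series' design text and was counted as a separate sample. Reads of immunoglobulin variable segments, which mark B cell clones, differed within the GAN vector libraries by no more than counting error (53 segments, 1239 reads, chi-square per degree of freedom 1.18, permutation p = 0.096). The same held within the sIL1RAP libraries (31 segments, 608 reads, 1.20, permutation p = 0.13), while GAN vector 1 and sIL1RAP 1 differed (2.66, permutation p = 2e-05). The 3 chow libraries differed from each other (15 segments, 230 reads, 2.09, permutation p = 0.00063), and chow replicates 1 and 2 held too few such reads to tell (3 segments, 31 reads, 1.92, permutation p = 0.17). Differences near counting error and alike segment use are also what pooled tissue or repeat libraries of the same mouse would give. These values do not exclude either. Every p, and every SD read as a spread between mice, holds only if the libraries of a group are separate mice. The ribosomal RNA gene CT010467.1, chosen after its values were seen, took 7.90% of the counts in sIL1RAP replicate 1, 1.19% and 1.59% in sIL1RAP replicates 2 and 3, and 0.336% to 0.752% in the other libraries. Mitochondrial transcripts took 6.44% to 6.52% of the counts in the sIL1RAP libraries and 7.01% to 9.02% in the others.

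**Figure D1:**
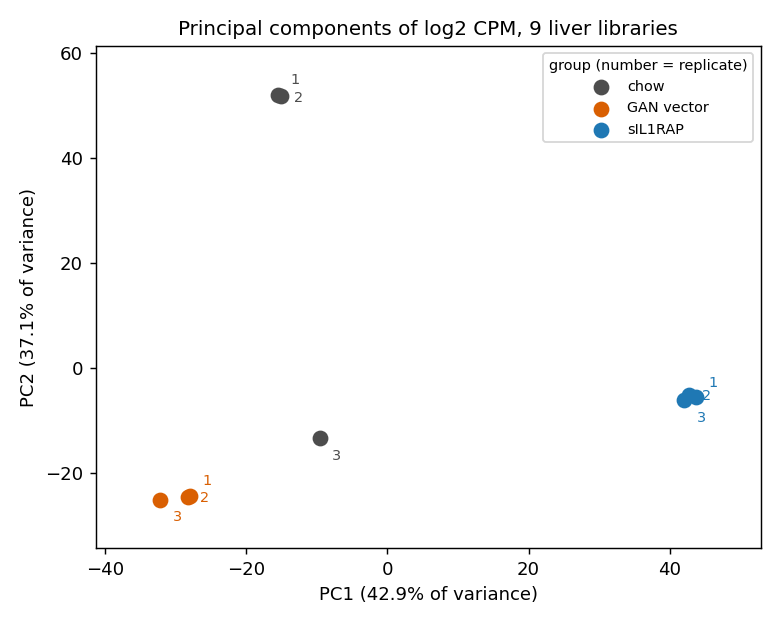
Scores of the 9 liver libraries on the first and second principal components of log2 CPM over 13522 genes (points, coloured by group, numbered by replicate; axes give the share of variance, 42.9% and 37.1%). Chow replicates 1 and 2 lie at PC2 scores of 52.1 and 51.8, chow replicate 3 at -13.4 and the GAN vector libraries between -25.0 and -24.3.

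The comparison of GAN vector with chow asks what the diet changed in the liver. The sources used here name a vector for the GAN groups and none for chow, so diet and vector injection cannot be separated, and differences given to the diet below belong to both. Macrophage transcripts rose with the diet: Lyz2, the lysozyme of macrophages and neutrophils, went from 99.9 ± 1.15 to 215 ± 5.27 CPM (SD, n = 3). Adgre1, which encodes the F4/80 antigen, rose 2.65-fold (log2 SE 0.10), and Cybb, a subunit of the phagocyte NADPH oxidase, rose 2.47-fold (log2 SE 0.11). The inflammasome sensor Nlrp3 rose 3.43-fold and the cytokine Il1b rose 2.24-fold. Squalene epoxidase, Sqle, an enzyme of cholesterol synthesis, fell from 26.3 ± 22.1 to 0.202 ± 0.0609 CPM. In all, 3828 of 13522 genes changed, 1844 higher and 1984 lower, of which 271 were higher and 314 lower by 2-fold or more. Without chow replicate 3 the count was 7798, 3842 higher and 3956 lower, and 3800 genes were called with and without it, all 3800 in the same direction. Leaving out chow replicate 1 or 2 gave 2089 and 2088 genes, and leaving out GAN vector replicate 1, 2 or 3 gave 2151, 2025 and 1932.

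The 10 largest rises were led by Art2b, an ADP-ribosyltransferase of T cells (5.32-fold, log2 SE 0.52, adjusted p = 0.0116), and Clec4e, the macrophage receptor Mincle (5.05-fold, log2 SE 0.60, adjusted p = 0.0213). The guanylate-binding protein gene Gbp2b rose 4.42-fold, the copper transporter gene Atp7a 4.38-fold and the cadherin gene Cdh18 4.22-fold. Rnf125, which encodes a ubiquitin ligase (ENSMUSG00000033107, chromosome 18, 20944625 to 20983862, plus strand), went from 40.9 ± 6.29 to 156 ± 2.33 CPM (log2 fold change 1.93, SE 0.10, adjusted p = 7.48e-06). Clec4d, Hgf (hepatocyte growth factor), Tlr4 (the endotoxin receptor) and the kinase gene Hipk2 rose by 1.91, 1.85, 1.84 and 1.79 on the log2 scale. Chow replicate 3 stood at 101 CPM for Lyz2 and 7.01 for Hgf, beside 99.3 and 7.18 in the mean of chow replicates 1 and 2. Cdh18 lost its call without any 1 of the other 8 libraries (adjusted p = 0.0751 to 0.122). Clec4e lost it without chow replicate 1 (0.0659) or GAN vector replicate 1, 2 or 3 (0.0613, 0.0525 and 0.0695).

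Among the falls, Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192, plus strand) changed by a log2 fold change of -6.97 (SE 1.67, adjusted p = 0.0247). The cytochrome P450 gene Cyp2c40 followed at -3.97, the metallothionein Mt1 at -3.75, the carboxylesterase Ces2b at -3.51 and the trefoil peptide Tff3 at -3.24. Cyp2c69 changed by -3.18, the hepcidin paralog Hamp2 by -2.75, the sterol dehydrogenase Nsdhl by -2.62, Selenbp2 by -2.51 and the transducin Gnat1 by -2.47. Chow replicate 3 lay near the GAN vector level for several of these genes. Sqle stood at 39.0 CPM in the mean of chow replicates 1 and 2, 0.827 in chow replicate 3 and 0.202 in GAN vector, Mt1 at 161, 13.6 and 8.29, and Selenbp2 at 1150, 231 and 148. Sqle, Cyp2c40, Mt1, Ces2b, Tff3, Nsdhl and Selenbp2 lost their calls without chow replicate 1 or 2 or GAN vector replicate 1, 2 or 3 (adjusted p = 0.0516 to 0.106). Nsdhl lost it also without sIL1RAP replicate 2 or 3 (0.0578 and 0.0525), and Gnat1 without chow replicate 1 (0.0527) or GAN vector replicate 1 or 2 (0.0580 and 0.0620). Members of close gene families (Mt1, Cyp2c40, Cyp2c69, Hamp2, Selenbp2, Ces2b, Art2b and Gbp2b here, Acot1, Acot3, Tgtp1, Ckmt1 and Cyp2b9 in the other comparison) can share reads with their paralogs, so their folds are uncertain.

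Of the 37 gene lists tested, 12 were higher and 5 lower in GAN vector than in chow with camera's preset correlation, and 0 passed with an estimated correlation. Without chow replicate 3, 21 lists passed with the preset and 13 of them also with the estimated correlation. NF-kB target genes were higher as a list (median log2 fold change 0.39, adjusted p = 0.00419, adjusted p = 0.520 with an estimated correlation): 8 of 32 rose, 2 fell and 22 did not pass, with 10 past the threshold when adjusted over the list alone. Tnfaip3 and Relb, regulators within the pathway, rose by 0.89 and 0.79 on the log2 scale, and Tlr2 and Il1a rose 1.81-fold and 1.54-fold. Nfkbia, the inhibitor of NF-kB, fell by 0.41 on the log2 scale. Tnfaip3 lost its call without chow replicate 1 or 2 or any GAN vector replicate (adjusted p = 0.0590 to 0.0993), Relb and Il1r1 without any 1 library but chow replicate 3 (0.0624 to 0.151), and Il1a without GAN vector replicate 2 (0.0508). Tnf (log2 fold change 0.50, adjusted p = 0.507) and Ccl2 (1.29, adjusted p = 0.221) did not pass, and Ccl2 stood at 0.595 CPM in the mean of chow replicates 1 and 2 and 6.03 in chow replicate 3. In the IL-1 family and inflammasome list, 7 of 15 genes rose and 3 fell (median log2 fold change 0.47, adjusted p = 0.0275, adjusted p = 0.518 with an estimated correlation), and 10 passed when adjusted over the list alone. Il1rn, the IL-1 receptor antagonist, rose 2.24-fold, Il18bp, the decoy receptor of IL-18, 1.89-fold and Casp1 1.60-fold, and Il1r1 fell by 0.70 on the log2 scale. On TPM values the median of this list was 0.31. This list's call ended without chow replicate 3 (adjusted p = 0.241). In that fit 22 of 32 NF-kB targets rose and 2 fell (median log2 fold change 0.91, adjusted p = 8.03e-05, adjusted p = 0.0704 with an estimated correlation), Ccl2 by 3.34 and Tnf by 1.42 on the log2 scale (adjusted p = 1.43e-13 and 0.0319). The number of NF-kB targets that rose was 4 without chow replicate 1, chow replicate 2 or GAN vector replicate 1, and 3 and 5 without GAN vector replicates 2 and 3. Omitting any library but chow replicate 3 left 1 IL-1 family gene fallen.

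Several lists of immune cell markers were higher. Of 20 monocyte and macrophage markers 14 rose and 0 fell (median log2 fold change 0.66, adjusted p = 3.56e-10, adjusted p = 0.271 with an estimated correlation). Of 14 Kupffer cell markers 6 rose, including Cd5l at 1.87-fold, and 0 fell (adjusted p = 0.000214, adjusted p = 0.520 with an estimated correlation). Without chow replicate 3 the Kupffer list split into 7 higher and 6 lower and no longer passed (adjusted p = 0.526). Chemokines and their receptors were higher as a list (6 of 26 rose, 1 fell, adjusted p = 0.00143, adjusted p = 0.520 with an estimated correlation), with Ccr5 up 2.24-fold. Of 14 dendritic cell and MHC class II genes 3 rose, among them Ciita, the activator of MHC class II genes, at 2.86-fold (adjusted p = 0.00181, adjusted p = 0.520 with an estimated correlation). T and NK cell markers passed as a list with 1 of 18 genes risen, 0 when adjusted over the list alone (adjusted p = 0.0460, adjusted p = 0.520 with an estimated correlation). That call ended without chow replicate 1 or 2 or GAN vector replicate 1 (adjusted p = 0.0906, 0.0950 and 0.0667). Neutrophil markers were higher (3 of 8 rose, S100a8 by 1.92-fold, adjusted p = 0.0260, adjusted p = 0.518 with an estimated correlation), a call that ended without chow replicate 3 or GAN vector replicate 1 (adjusted p = 0.129 and 0.0504). Leaving out chow replicate 3 raised the counts to 19 of 27 for chemokines (2 fell, median log2 fold change 1.31), 12 of 16 for dendritic cell genes (median 1.83) and 9 of 19 for T and NK cell markers (median 0.78), with adjusted p = 0.0204, 0.0459 and 0.0704 with an estimated correlation, and 0.0193 for the monocyte and macrophage list. Leaving out chow replicates 1 and 2 and GAN vector replicates 1, 2 and 3 in turn left 10, 10, 9, 9 and 9 monocyte and macrophage markers, 2, 3, 2, 3 and 3 chemokine genes and 2, 2, 1, 1 and 1 dendritic cell genes risen. Of the T and NK cell markers 0 rose without GAN vector replicate 1 or 3. On TPM values the medians of the T and NK cell and neutrophil lists were 0.23 and 0.33 on the log2 scale, against 0.42 and 0.66 with TMM. Removing the trend with length and GC content gave the Kupffer list a median of 0.42, against 0.26. Red blood cell transcripts, which follow the blood left in the tissue, had a median log2 fold change of 0.38 and did not pass (adjusted p = 0.0541, and 0.0445 without GAN vector replicate 3). All 9 of 9 rose without chow replicate 3 (median log2 fold change 1.47, adjusted p = 3.93e-07, adjusted p = 0.0193 with an estimated correlation). The haemoglobin gene Hbb-bs, chosen after its values were seen, stood at 217 CPM in the mean of chow replicates 1 and 2, 641 in chow replicate 3 and 699 ± 6.53 in GAN vector. The share of the immune cell differences that comes from blood was not tested.

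In the fibrosis and matrix list 8 of 35 genes rose and 1 fell (median log2 fold change 0.38, adjusted p = 0.00491, adjusted p = 0.520 with an estimated correlation), and 13 passed when adjusted over the list alone. The matrix protease gene Mmp14 was 1.69-fold and the proteoglycan genes Dcn and Lum 1.54-fold and 1.49-fold higher. Col1a1, the main fibrillar collagen gene, is named after its value was seen and did not pass (log2 fold change 0.49, adjusted p = 0.305). Sinusoidal endothelial markers (9 of 19 rose, adjusted p = 3.50e-06, adjusted p = 0.520 with an estimated correlation) and quiescent stellate cell markers (5 of 15 rose, 1 fell, adjusted p = 0.0192, adjusted p = 0.520 with an estimated correlation) were higher. Genes of the unfolded protein response were also higher (3 of 23 rose, 1 fell, adjusted p = 0.0146, adjusted p = 0.611 with an estimated correlation), with the chaperone genes Hyou1 up 2.01-fold and Pdia4 up 1.44-fold, and 0 passed when adjusted over the list alone. In the fit without chow replicate 3, 21 of 35 matrix genes rose and 2 fell, 14 of 19 endothelial markers rose and 1 fell (median log2 fold change 0.30, against 0.50), 9 of 15 stellate markers rose and 1 fell, and 19 of 23 unfolded protein genes rose and 1 fell (median log2 fold change 0.57). Their adjusted p with an estimated correlation were 0.0758, 0.0459, 0.0724 and 0.0193, and 20 unfolded protein genes passed when adjusted over the list alone. Leaving out chow replicates 1 and 2 and GAN vector replicates 1, 2 and 3 in turn left 3, 3, 3, 2 and 3 matrix genes, 2, 2, 3, 2 and 3 stellate markers and 0 unfolded protein genes risen. Leaving out any sIL1RAP replicate left 3 stellate markers. The matrix median was 0.23 on TPM values and 0.24 without chow replicate 1, and the stellate median was 0.11 without chow replicate 2. The stellate and unfolded protein calls ended without chow replicate 1 (adjusted p = 0.0534 and 0.0980) or 2 (0.0639 and 0.0585). Hyou1 and Pdia4 lost their calls without chow replicate 1 or 2 or any GAN vector replicate (0.0567 to 0.0870), and Dcn without chow replicate 2 or GAN vector replicate 2 or 3 (0.0516 to 0.0532).

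The 5 lower lists were those of cholesterol synthesis, interferon-stimulated, hepatocyte identity, male-biased and complement and coagulation genes. Lists of lipogenesis, fatty acid oxidation, bile acid, xenobiotic and glucose genes did not pass, with median log2 fold changes of -0.07 to 0.09. Lists of lipid droplet, lipid-associated macrophage, NRF2 and acute phase genes did not pass either (adjusted p = 0.0887, 0.0887, 0.0552 and 0.148). They passed with the preset correlation without chow replicate 3 (4.33e-07, 0.000167, 0.000372 and 0.000241). There 13 of 17 lipid droplet, 12 of 18 macrophage and 15 of 21 NRF2 genes rose and 2, 2 and 1 fell. Of 28 acute phase genes 19 fell and 8 rose. Of 26 cholesterol synthesis genes 12 fell and 3 rose (median log2 fold change -0.77, adjusted p = 0.00194, adjusted p = 0.611 with an estimated correlation), with Hmgcs1 at -0.75 and Lss at -0.65, and 24 passed when adjusted over the list alone. Without chow replicate 3, 21 of them fell (adjusted p = 8.2e-10, adjusted p = 0.0193 with an estimated correlation). Of 34 interferon-stimulated genes 13 fell and 1 rose (adjusted p = 0.000429, adjusted p = 0.520 with an estimated correlation), with Isg15 at -0.88 and the MHC class I gene H2-K1 at -0.50. Hepatocyte identity genes were lower (13 of 24 fell, 1 rose, adjusted p = 0.00194, adjusted p = 0.520 with an estimated correlation), the urea cycle gene Ass1 at -0.95. Male-biased liver genes (10 of 23 fell, 3 rose, adjusted p = 0.0328, adjusted p = 0.520 with an estimated correlation) and complement and coagulation genes (9 of 27 fell, 4 rose, adjusted p = 0.0425, adjusted p = 0.527 with an estimated correlation) were lower too. With chow replicate 3 left out, 26 of 34 interferon-stimulated genes fell and 3 rose, 15 of 23 male-biased genes fell and 4 rose, and 18 of 27 complement and coagulation genes fell and 6 rose (adjusted p = 0.0554, 0.0204 and 0.0459 with an estimated correlation). Leaving out chow replicates 1 and 2 and GAN vector replicates 1, 2 and 3 in turn left 7, 6, 6, 6 and 6 interferon-stimulated genes, 8, 9, 7, 7 and 6 hepatocyte identity genes and 2, 2, 3, 2 and 2 cholesterol synthesis genes fallen. The same omissions left 2 male-biased genes each, and 5, 5, 5, 5 and 4 complement and coagulation genes. Leaving out sIL1RAP replicates 1, 2 and 3 left 8, 7 and 7 cholesterol synthesis and 5, 5 and 6 male-biased genes. The lipid droplet and NRF2 lists passed with the preset correlation without GAN vector replicate 3 (adjusted p = 0.0445 and 0.0418), and the NRF2 list without sIL1RAP replicate 2 (0.0490). The male-biased and complement calls ended without chow replicate 1 (adjusted p = 0.0930 and 0.104), chow replicate 2 (0.0638 and 0.0804) or GAN vector replicate 1 (0.0716 and 0.0667), and the complement call also without GAN vector replicate 2 (0.0505). Cd36, a fatty acid transporter, and Gpnmb, a marker of lipid-associated macrophages, were chosen after their values were seen. Cd36 stood at 36.5 CPM in the mean of chow replicates 1 and 2, 191 in chow replicate 3 and 315 ± 14.7 in GAN vector (adjusted p = 0.0782, and 2.76e-27 without chow replicate 3). Gpnmb stood at 0.243, 8.08 and 11.7 ± 1.12 CPM (adjusted p = 0.163, and 4.81e-18 without chow replicate 3).

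**Figure D2:**
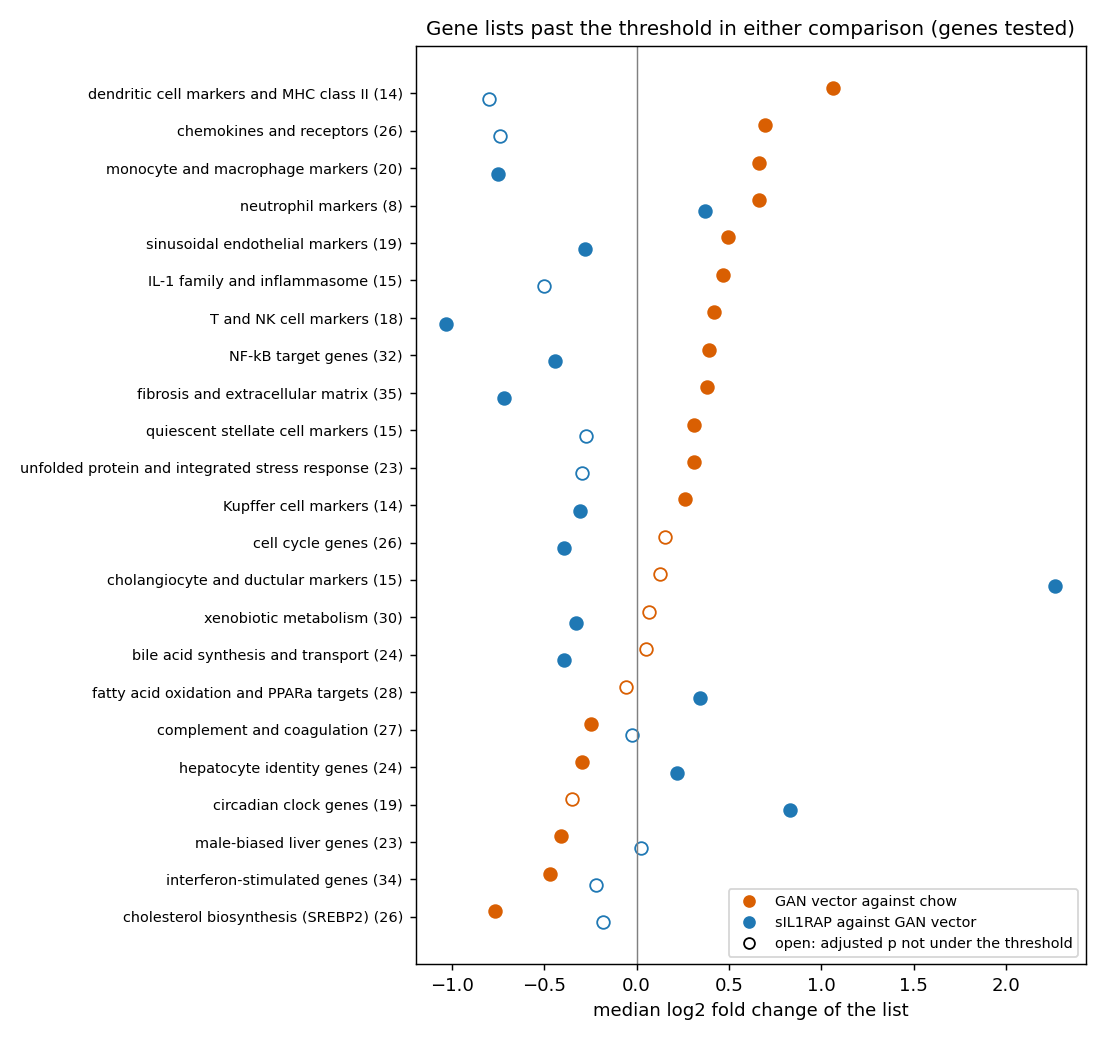
Median log2 fold change (x axis) of each gene list past the threshold in either comparison (rows, number of genes tested in brackets), for GAN vector against chow (orange) and sIL1RAP against GAN vector (blue); filled points have an adjusted p under 0.05 with camera's preset correlation, and none kept it with an estimated correlation. Monocyte and macrophage markers lie at 0.66 and -0.75, cholangiocyte markers at 0.13 and 2.26.

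The comparison of sIL1RAP with GAN vector asks what AAV-sIL1RAP changed in livers on the GAN diet, above all in inflammation and NF-kB programmes. Macrophage and T cell transcripts fell: Adgre1 was 2.66-fold lower (log2 SE 0.10), Cybb 2.24-fold lower (log2 SE 0.11), and the cytotoxic T cell gene Cd8a went from 1.51 ± 0.325 to 0.239 ± 0.0808 CPM (SD, n = 3). Cxcl9, an interferon-induced chemokine, was 6.54-fold lower and Nlrp3 2.62-fold lower. Chemokines and their receptors did not pass as a list (7 of 26 fell, 2 rose, adjusted p = 0.244 with camera's preset correlation, and 0.00510 without chow replicate 3). Clock genes moved apart, with Arntl (the clock activator BMAL1) 8.85-fold lower and Dbp, a clock output gene picked after its values were seen, rising from 2.33 ± 0.585 to 67.0 ± 3.59 CPM. Epithelial genes nearly without reads in GAN vector rose, and the mucin-like gene Dmbt1 reached 162 ± 8.26 CPM. In all, 5966 of 13522 genes changed, 2910 higher and 3056 lower, of which 443 were higher and 641 lower by 2-fold or more. On the deposited TPM values, where the median of all genes moved from a log2 fold change of -0.03 to -0.14, limma called 3727 genes, 967 higher and 2760 lower.

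The 10 largest rises were mostly genes with few or no reads in GAN vector. Dmbt1 (ENSMUSG00000047517, chromosome 7, 131032046 to 131121628, plus strand) had 11290 reads in the sIL1RAP libraries and 2 in GAN vector, a ratio of 4429 (95% interval 1226 to 36576). The creatine kinase gene Ckmt1 (372 reads against 0) was 97.3-fold higher against the floor of 3 reads (exact 95% lower limit 78.7). Spink4, a goblet cell peptide, was 81.9-fold higher against that floor (313 reads against 0, exact 95% lower limit 66.2). The ratio was 179 for Cnn1, a smooth muscle calponin (95% interval 31.8 to 7096), and 178 for the epithelial stem cell gene Olfm4 (31.6 to 7065). It was 173 for the oxidase gene Duox2 (30.8 to 6879) and 90.5 for the GABA receptor subunit gene Gabrp (30.7 to 441). The protease Mmp7, lactoferrin (Ltf) and the neutrophil chemokine Cxcl5 rose by 6.12, 5.68 and 5.57 on the log2 scale. The 3 sIL1RAP libraries were alike, with Cxcl5 at 16.1 ± 0.874 CPM. Pooled tissue or repeat libraries of the same mouse would give such likeness too.

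Among the largest falls, the retinoic acid hydroxylase genes Cyp26a1 and Cyp26b1 went from 22.4 ± 1.44 to 1.05 ± 0.113 CPM and from 21.3 ± 0.701 to 1.88 ± 0.264 CPM (adjusted p = 0.0283 and 0.00616). Cyp26a1 and Cyp2b9 lost their calls without any 1 GAN vector or sIL1RAP replicate (adjusted p = 0.0531 to 0.0885). Those fits, like every fit here without 1 GAN vector or sIL1RAP replicate, take the spread from all 3 groups, chow replicate 3 included. Npas2, a partner of BMAL1, fell 14.4-fold, Cyp2b9 12.7-fold and Lrtm1 8.37-fold. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand) had a log2 fold change of -3.15 (SE 0.16, adjusted p = 1.12e-06). The interferon-induced GTPase gene Tgtp1 fell 7.56-fold and Fgf21, a liver hormone of fasting and stress, 7.29-fold. Rnf125 went from 156 ± 2.33 to 24.9 ± 0.525 CPM (log2 fold change -2.65, SE 0.10, adjusted p = 1.66e-07).

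NF-kB target genes were lower as a list (median log2 fold change -0.44, adjusted p = 0.0441, adjusted p = 0.682 with an estimated correlation): 11 of 32 fell, 3 rose and 18 did not pass, with 14 past the threshold when adjusted over the list alone. Cxcl10 fell by 1.71 on the log2 scale, Tnfaip2 by 1.24, Tnfaip3 by 0.99, Il1a by 0.97, Rel by 0.81 and Il1b by 0.60, the last losing its call without GAN vector replicate 2 or sIL1RAP replicate 2 (adjusted p = 0.0531 and 0.0510). Nfkbia rose 1.46-fold and Sod2, a mitochondrial superoxide dismutase, 1.29-fold. The chemokine gene Ccl20 had 57 reads against 2 (ratio 22.4, 95% interval 5.91 to 189). Tnf (log2 fold change -0.41, adjusted p = 0.552) and Ccl2 (-1.92, adjusted p = 0.0755) did not pass with all 9 libraries, and Ccl2 did without chow replicate 3. Of the 32 targets, without chow replicate 3, 20 fell and 3 rose (adjusted p = 0.00529, adjusted p = 0.125 with an estimated correlation). The list's call ended without sIL1RAP replicate 2, where 7 fell (median log2 fold change -0.40, adjusted p = 0.0569), and over all alternatives its adjusted p ran from 0.00452 to 0.682. NF-kB pathway components went both ways, with 6 of 27 higher and 7 lower, and did not pass as a list (adjusted p = 0.819). In the IL-1 family list 6 of 15 genes fell and Il1rap alone rose, and the list did not pass (adjusted p = 0.488). Its falls were Nlrp3 at -1.39, Il18bp at -1.13, Il1a at -0.97, Casp1 at -0.85, Il33 at -0.73 and Il1b at -0.60.

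Of 20 monocyte and macrophage markers 15 fell and 0 rose (median log2 fold change -0.75, adjusted p = 2.51e-05, adjusted p = 0.194 with an estimated correlation). Lyz2 went from 215 ± 5.27 to 138 ± 11.5 CPM, and Mpeg1, a pore-forming protein of macrophages, fell by 0.97 on the log2 scale. Of 18 T and NK cell markers 10 fell (adjusted p = 0.0125, adjusted p = 0.495 with an estimated correlation), with Cd8a 6.35-fold, Cd8b1 5.42-fold and Cd4 2.48-fold lower, though Cd8b1 lost its call without sIL1RAP replicate 1 (adjusted p = 0.0509). Of 14 Kupffer cell markers 5 fell, Cd5l by 0.80 on the log2 scale (adjusted p = 0.0286, adjusted p = 0.671 with an estimated correlation), and this call ended without chow replicate 3, where 9 fell and 4 rose (adjusted p = 0.0712). Omitting GAN vector replicate 2 or sIL1RAP replicate 3 left 3 Kupffer cell markers fallen. T and NK cell markers that fell numbered 14 without chow replicate 3, and 5, 7, 5, 3, 5 and 6 without GAN vector replicates 1 to 3 and sIL1RAP replicates 1 to 3 in turn. Neutrophil markers were higher as a list (median log2 fold change 0.37, adjusted p = 0.0175, adjusted p = 0.194 with an estimated correlation): 3 of 8 rose, Ltf, S100a8 by 1.80-fold and S100a9 by 1.48-fold. Ltf, among the 10 largest rises together with epithelial genes, rose far more than S100a8 and S100a9. The list was not tested without it, here or against chow. On TPM values the medians of the T and NK cell and Kupffer lists were -0.58 and -0.46, against -1.03 and -0.31 with TMM, and the Kupffer median was -0.54 with the trend with length and GC content removed. The median of the neutrophil list was -0.03 on TPM values, 0.21 with that trend removed and 0.13 to 0.21 on the log2 scale without chow replicate 1 or 3, GAN vector replicate 1 or 3 or any sIL1RAP replicate, and its call ended without chow replicate 3 (adjusted p = 0.0730). Red blood cell transcripts had a median log2 fold change of -0.71 and did not pass (2 of 9 fell, 1 rose, adjusted p = 0.325), and without chow replicate 3, 6 of 9 fell (adjusted p = 0.00262, adjusted p = 0.0699 with an estimated correlation). Among them Bpgm, an enzyme of red blood cells, was 1.36-fold lower, and Hbb-bs was 2.48-fold lower, a call lost without any 1 GAN vector or sIL1RAP replicate (adjusted p = 0.0770 to 0.0958). How far less blood in the tissue accounts for the fall of immune cell markers was not tested.

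Of 35 fibrosis and matrix genes 22 fell and 2 rose (median log2 fold change -0.72, adjusted p = 0.00388, adjusted p = 0.539 with an estimated correlation), and 24 passed when adjusted over the list alone. Lum was 2.16-fold and the basement membrane collagen gene Col4a1 1.64-fold lower, and Col1a1, named after its value was seen, was 2.43-fold lower, a call lost without GAN vector replicate 2 or sIL1RAP replicate 2 (adjusted p = 0.0512 and 0.0576). The risers were the smooth muscle and myofibroblast genes Acta2, from 2.04 ± 0.172 to 14.0 ± 1.13 CPM, and Tagln, 2.42-fold higher. Pieces of gallbladder or large bile duct wall, taken up below, could bring smooth muscle and are not excluded as the source of both rises. Sinusoidal endothelial markers were lower (8 of 19 fell, adjusted p = 0.0441, adjusted p = 0.746 with an estimated correlation), with 13 fallen without chow replicate 3 and 5 without sIL1RAP replicate 1. Their median was -0.28, and -0.43 on TPM values. Cell cycle genes were lower (11 of 26 fell, adjusted p = 0.0416, adjusted p = 0.539 with an estimated correlation), with the proliferation marker Mki67 4.60-fold, the topoisomerase Top2a 4.39-fold and the mitotic kinesin Kif11 2.73-fold down.

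Cholangiocyte and ductular markers were higher as a list (median log2 fold change 2.26, adjusted p = 2.74e-06, adjusted p = 0.194 with an estimated correlation), with 8 of 15 risen and 3 fallen. On TPM values the median was 0.63. The duct keratin Krt19 went from 0.318 ± 0.137 to 13.7 ± 0.315 CPM, Muc1 was 29.5-fold and Prom1 6.27-fold higher, and Pkhd1, the fibrocystin gene, was 2.86-fold lower. Fatty acid oxidation and PPARα target genes were higher (14 of 28 rose, 3 fell, adjusted p = 0.00366, adjusted p = 0.150 with an estimated correlation). Among them the thioesterase genes Acot3 and Acot1 rose 11.7-fold and 4.13-fold and the dehydrogenase gene Acadvl 1.67-fold, while the kinase gene Pdk4 was 3.08-fold lower. Hepatocyte identity genes were higher (10 of 24 rose, 2 fell, adjusted p = 0.0497, adjusted p = 0.682 with an estimated correlation), among them the transcription factor gene Cebpa at 1.92-fold. On TPM values the medians of the fatty acid oxidation and hepatocyte identity lists were 0.16 and 0.05 on the log2 scale, against 0.34 and 0.22 with TMM, and the latter was 0.12 with the trend with length and GC content removed. With chow replicate 3 omitted, 22 of 28 fatty acid oxidation genes rose and 3 fell, 18 of 24 bile acid genes fell and 5 rose, 17 of 30 xenobiotic genes fell and 7 rose, and 15 of 24 hepatocyte identity genes rose and 5 fell. None of these lists passed there with an estimated correlation (adjusted p = 0.0699 to 0.250). Without GAN vector replicate 3, 2 xenobiotic genes rose. The hepatocyte identity call ended without GAN vector replicate 3 (adjusted p = 0.0619) or sIL1RAP replicate 2 (0.0534). Of 24 bile acid genes 9 fell and 2 rose (adjusted p = 0.0125, adjusted p = 0.150 with an estimated correlation), with the canalicular pumps Abcc2 2.03-fold and Abcb11 1.75-fold lower. Of 30 xenobiotic metabolism genes 13 fell and 4 rose (adjusted p = 0.0166, adjusted p = 0.150 with an estimated correlation), with the bilirubin transferase Ugt1a1 at -1.49 and Cyp3a11 at -0.86 on the log2 scale, and the median of the list was -0.33, and -0.49 on TPM values.

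Clock genes moved in both directions and were higher as a list (11 of 19 rose, 5 fell, median log2 fold change 0.83, adjusted p = 0.00667, adjusted p = 0.150 with an estimated correlation), and 17 passed when adjusted over the list alone. Without GAN vector replicate 1 or 3 or sIL1RAP replicate 1 or 3, 3 clock genes fell. Usp2 rose 24.4-fold, Dbp 28.8-fold and Per1 7.56-fold, while Arntl, Npas2 and Clock (2.12-fold) fell. Dbp stood at 11.9 and 11.5 CPM in chow replicates 1 and 2 and 3.02 in chow replicate 3. With camera's preset correlation 14 of 37 lists passed in this comparison, 5 higher and 9 lower, and with an estimated correlation 0 passed.

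**Figure D3:**
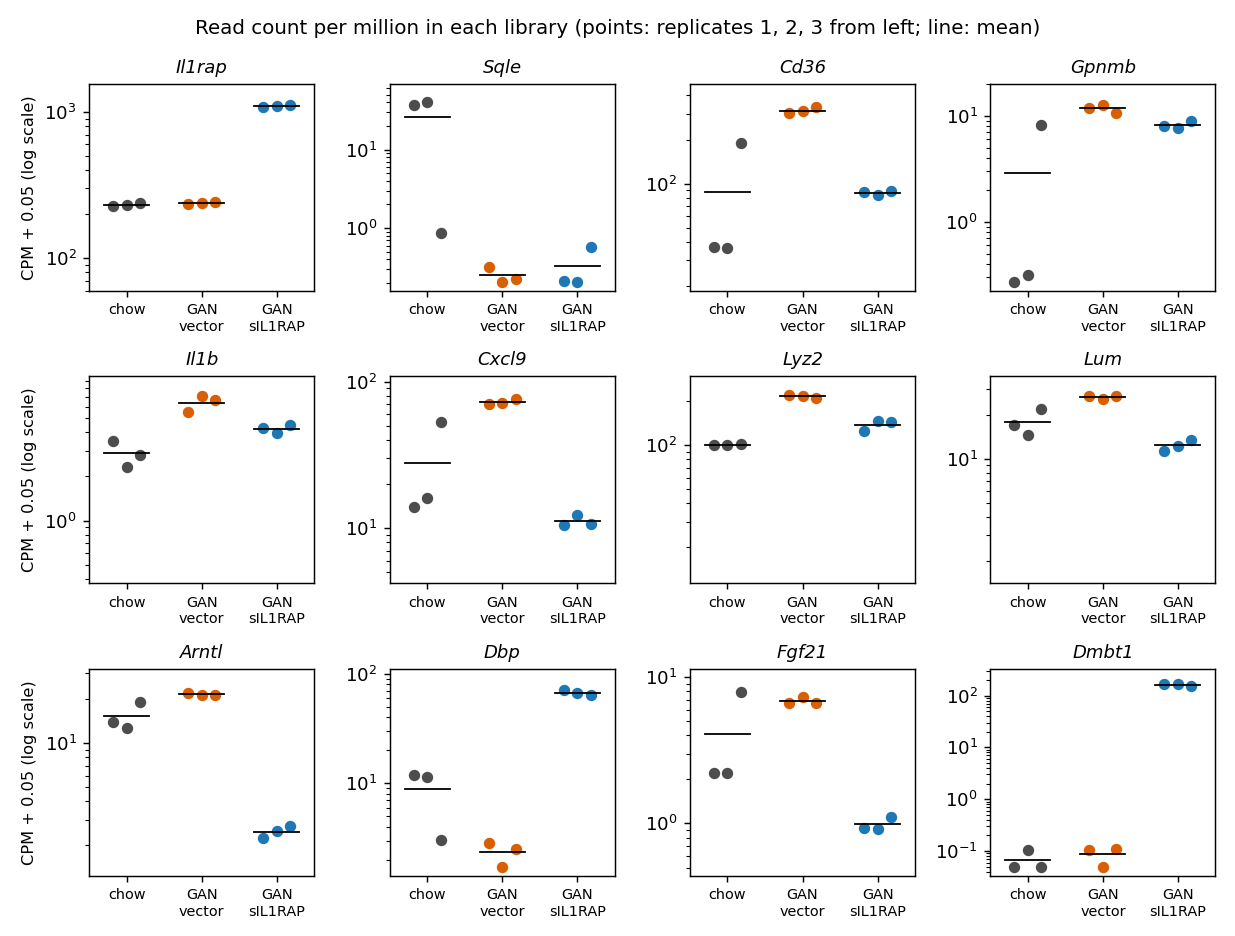
Level of 12 genes in each library (points, replicates 1 to 3 from left to right within a group; line, group mean; y axis, CPM plus 0.05 on a log scale). Il1rap and Dmbt1 are high in the 3 sIL1RAP libraries alone, at 1097 and 162 CPM on average, and chow replicate 3 lies near the GAN vector level for Sqle, Cd36 and Gpnmb but at the chow level for Lyz2.

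The comparison of sIL1RAP with chow shows how far treated livers stood from chow livers. The thioesterase genes Acot3 and Acot1 were 22.1-fold and 3.16-fold higher than in chow (log2 SE 0.37 and 0.09), the calprotectin gene S100a8 3.45-fold and Krt19 26.1-fold higher (log2 SE 0.18 and 0.19). Hmgcs1, an early enzyme of cholesterol synthesis, went from 199 ± 53.7 to 62.9 ± 1.14 CPM (SD, n = 3), and Isg15 was 1.42-fold lower, a call lost without chow replicate 1 or 2 or sIL1RAP replicate 1 or 2 (adjusted p = 0.0530 to 0.0640). Of 26 cholesterol synthesis genes 17 fell and 0 rose (adjusted p = 1.05e-07, adjusted p = 0.550 with an estimated correlation). Interferon-stimulated genes (21 of 34 fell, 1 rose, adjusted p = 2.37e-07, adjusted p = 0.419 with an estimated correlation) and acute phase proteins (15 of 28 fell, 2 rose, adjusted p = 0.00120, adjusted p = 0.459 with an estimated correlation) were lower. Male-biased genes (7 of 23 fell, adjusted p = 0.00466, adjusted p = 0.459 with an estimated correlation) and bile acid genes (9 of 24 fell, adjusted p = 0.0364, adjusted p = 0.218 with an estimated correlation) were lower as well. Fatty acid oxidation genes (14 of 28 rose, 2 fell, adjusted p = 3.34e-05, adjusted p = 0.0384 with an estimated correlation) and neutrophil markers (4 of 8 rose, adjusted p = 1.05e-07, adjusted p = 0.0384 with an estimated correlation) were higher with either correlation, though the neutrophil list did not pass with the estimated correlation without chow replicate 3 (adjusted p = 0.123). Cholangiocyte markers (8 of 15 rose, 2 fell, adjusted p = 3.5e-12, adjusted p = 0.0595 with an estimated correlation) and clock genes (10 of 19 rose, 3 fell, adjusted p = 0.0364, adjusted p = 0.218 with an estimated correlation) were higher with the preset correlation alone. Without chow replicate 3 the estimated correlation gave the cholangiocyte list an adjusted p of 0.0388, the cholesterol list 0.00713, acute phase proteins 0.0278, male-biased genes 0.0351 and interferon-stimulated genes 0.0558. In that fit 15 male-biased genes fell and 4 rose, 13 bile acid genes fell and 6 rose, and 12 cholangiocyte markers rose. The lists of this comparison were not tested without the other libraries. In all, 4288 genes differed, 2036 higher and 2252 lower, and limma on TPM values called 2253, 359 higher and 1894 lower. The count was 8094 without chow replicate 3, 2712 and 2619 without chow replicates 1 and 2, and 2512 and 2493 without sIL1RAP replicates 1 and 2.

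Genes changed by the diet were then compared with those changed by AAV-sIL1RAP. Art2b rose 5.32-fold with the diet and was 5.64-fold lower with sIL1RAP, Gbp2b went 4.42-fold up and 4.40-fold down, and Atp7a 4.38-fold up and 4.75-fold down. The clock gene Per1 was 5.04-fold lower with the diet and 7.56-fold higher with sIL1RAP, the lectin gene Lgals4 4.71-fold lower and 4.96-fold higher, and Lpin1, which encodes a phosphatidate phosphatase, 4.43-fold lower and 4.49-fold higher. Chow replicate 3 stood at 1.51 CPM for Per1, 4.87 for Lgals4 and 14.1 for Lpin1, beside 9.53, 22.1 and 88.8 in the mean of chow replicates 1 and 2. Clic6, Epn3, Myo15b and Ccl28 complete the 10 with the largest smaller change and rest on few reads, with means of 0.103 to 0.477 CPM in chow, at most 0.0948 in GAN vector and 0.671 to 1.95 in sIL1RAP. Per1, Lgals4, Lpin1, Clic6 and Epn3 lost their diet calls in several of the fits without 1 library (chow replicates 1 and 2, GAN vector replicates 1 to 3, sIL1RAP replicates 1 to 3, adjusted p = 0.0505 to 0.137), and Ccl28 without GAN vector replicate 1 or 2 (0.0581 and 0.0610). Lpin1 also lost its call with sIL1RAP without any 1 GAN vector or sIL1RAP replicate (0.0561 to 0.0829). In all, 2372 genes passed in both comparisons in opposite directions, 1326 up then down and 1046 down then up, and 113 passed in the same direction. Independent lists of these sizes would share 417 and 427 genes up then down and down then up. The numbers without chow replicate 3 were 4308 and 1102, with 2409 up then down and 1899 down then up, against 1248 and 1180 for independent lists of that fit. Both comparisons use the GAN vector libraries: 20 simulated data sets with no group difference gave at most 1 such gene, and 20 with the diet difference alone gave at most 3. The fold changes correlated across genes at r = -0.475, against a mean of -0.514 in simulations without any difference, and their covariance was -0.191 against a simulated -0.031, a difference of -0.160. A share of 87.5% of the genes changed by diet had the opposite sign with sIL1RAP, against 62.7% in simulations with the diet difference alone. The share was 73.2% without chow replicate 3, a fit that was not simulated. The 3 GAN vector libraries cannot be split with at least 2 on each side, so part of the excess may come from the shared libraries. The simulated libraries held no offset common to the GAN vector livers alone, so they cannot exclude one. A difference in time of day or feeding state, raised below for the clock genes, was not tested for the genes changed in opposite directions. The count was 1468, 1374 and 1260 without GAN vector replicates 1, 2 and 3, and 1576 and 1562 without chow replicates 1 and 2. On TPM values it was 732, 535 up then down and 197 down then up.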

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

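The removal of the trend with length and GC content, the summing of chow replicates 1 and 2 and the removal of ribosomal RNA genes were chosen after the data were seen, and the other tests in this part before. RLE and upper quartile scaling, no filter, the stricter filter, DESeq2, limma-voom and the removal of ribosomal RNA genes gave 3460 to 3845 genes for GAN vector against chow, 5450 to 5975 for sIL1RAP against GAN vector, 3993 to 4308 for sIL1RAP against chow and 2047 to 2374 in opposite directions. Il1rap stayed higher with sIL1RAP under every alternative, at 2.19 to 2.23 when each library was left out. Of the list results, 0 and 0 lists passed with an estimated correlation, a setting that leaves every median as it was (NF-kB targets -0.44, adjusted p = 0.682), and fry called 23 lists for sIL1RAP against GAN vector. An added 2-fold threshold left 585, 1084 and 786 genes in the comparisons and 214 in opposite directions, by its construction. With the 6 libraries compared alone, 1912 genes passed for GAN vector against chow, 8314 for sIL1RAP against GAN vector and 2892 for sIL1RAP against chow. In that setting 22 lists passed for sIL1RAP against GAN vector. That fit leaves out chow replicate 3, and the omission of this library alone gave 8588 genes and 23 lists. The cause was not tested for the counts of the 6 libraries or for the TPM counts. On log2(TPM + 1) the counts were 1279, 3727, 2253 and 732 in opposite directions. On log2(TPM + 0.1) they were 1130, 3722, 2263 and 639, and on log2(TPM + 1) without a filter 245, 2900, 1348 and 184. On log2(TPM + 1), 967 of 3727, 359 of 2253 and 535 of 732 genes were higher (or up then down), against 2910 of 5966, 2036 of 4288 and 1326 of 2372 with edgeR, and without a filter 179 of 245 in the diet comparison, against 1844 of 3828. With chow replicates 1 and 2 summed, 2253 genes passed for GAN vector against chow, with fewer libraries in the fit. Removing the trend with length and GC content turned Il1rap in GAN vector against chow from 0.04 to -0.11, neither past the threshold, and the cause was not tested. With that removal 3570, 4960 and 4090 genes passed. Of the calls before it, 2832 (74.0%), 3844 (64.4%) and 3299 (76.9%) stayed in the same direction. Before the removal, fold changes of sIL1RAP against GAN vector correlated across genes with GC content (Spearman rho 0.365) and length (-0.314). Of the genes changed in opposite directions 58.2% stayed so, which leaves open how far such a trend contributes to them.

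Leaving out each library in turn gave 1932 (without GAN vector replicate 3) to 7798 genes (without chow replicate 3) for GAN vector against chow, 4413 to 8588 for sIL1RAP against GAN vector, 2493 (without sIL1RAP replicate 2) to 8094 (without chow replicate 3) for sIL1RAP against chow, and 1260 (without GAN vector replicate 3) to 4308 (without chow replicate 3) in opposite directions. Gene lists past the threshold numbered 12 to 21 for the diet and 13 to 23 (without chow replicate 3) for sIL1RAP, and the median of the NF-kB targets ran from -0.49 to -0.40, the latter without sIL1RAP replicate 2 and not past the threshold. Part of each fall in a count follows from fewer libraries, and dispersion fell to a coefficient of variation of 5.73% without chow replicate 3. For the genes named in the text, omissions left 430 of 558 calls the same in GAN vector against chow (122 weaker, 6 stronger), 824 of 855 in sIL1RAP against GAN vector (29 weaker, 2 stronger) and 50 of 54 in sIL1RAP against chow (4 weaker). Among these omissions, that of chow replicate 3 left 156 calls the same, 7 stronger and 0 weaker. The other settings left 698 of 849 (146 weaker, 4 stronger, 1 reversed), 1280 of 1302 (20 weaker, 2 stronger) and 82 of 84 (2 weaker). The replicate number as a block gave 3644, 5875, 4058 and 2302 genes, 18 and 13 lists, and a median of -0.44 for the NF-kB targets (adjusted p = 0.0371), while Cdh18, Nsdhl, Relb, Il1r1, Lpin1 and Epn3 lost their diet calls. Of 9 pairs of libraries with the same number, 1 deviated together by a correlation over 0.1 (range -0.017 to 0.152), and 8 of 9 libraries correlated best with their own number, a hint from the data and not from the design. The 6 libraries of a comparison have 10 splits with the real one included, too few for a share under 0.05: with all 9 libraries in each fit and the labels of those 6 alone exchanged, 1 split, the real one, gave 3828, 5966 and 4288 genes with edgeR, and the highest of the others gave 0. At these depths, genes with 3 or fewer reads in a group have no fold but a ratio with a wide interval or a lower bound.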

Other observations

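The tests of swapped labels, of mixed RNA, of a GAN-fed liver under a chow label, of small ducts and of both explanations for the clock genes, and the split of smooth muscle genes by level, were chosen after the results they bear on had been seen.

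Members of several further lists went both ways between sIL1RAP and GAN vector, and none of these lists passed with camera over all 9 libraries. Acute phase proteins had 7 fallen and 1 risen (adjusted p = 0.118), NRF2 genes 9 and 3 (0.194) and cholesterol synthesis genes 8 and 1 (0.0587). Dendritic cell and MHC class II genes did not go both ways, with 3 fallen and 0 risen, and did not pass either (0.0539). Without chow replicate 3 the acute phase, NRF2, cholesterol synthesis and dendritic cell lists passed with the preset correlation (adjusted p = 0.000271 to 0.0224). The dendritic cell list also passed without chow replicate 1 or 2, GAN vector replicate 1 or 3 or any sIL1RAP replicate (0.0178 to 0.0470). The cholesterol synthesis list also passed without sIL1RAP replicate 1 (0.0489). Of 34 interferon-stimulated genes 12 fell and 5 rose (adjusted p = 0.190), with the GTPase genes Gbp3 1.84-fold and Ifi47 1.63-fold lower and Bst2, the gene of tetherin, 1.62-fold higher. Of 23 genes of the unfolded protein response 8 fell and 4 rose (adjusted p = 0.194), with the chaperone gene Hspa5 2.38-fold and the transcription factor gene Atf4 1.62-fold lower and Herpud1 1.64-fold higher. B and plasma cell markers fell in 6 of 12 cases and rose in 1 (adjusted p = 0.141), Ms4a1 being 3.04-fold and Cd19 2.87-fold lower and Derl3 5.42-fold higher. Of 20 genes of glucose metabolism 8 rose and 3 fell (adjusted p = 0.0598), with the regulator Foxo1 1.79-fold and the gluconeogenic enzyme gene Fbp1 1.54-fold higher. Without chow replicate 3 the unfolded protein and B cell lists passed with the preset correlation (adjusted p = 0.0221 and 0.0224) and not with an estimated correlation (0.0918 and 0.133). The glucose list passed with the preset correlation without sIL1RAP replicate 1 (0.0496).

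Chow replicate 3 stood apart from the other chow libraries. A swap of labels with a GAN vector library is argued against, since each GAN vector library correlated better with its own group than with chow replicates 1 and 2, by at least 0.0316. A mixture of GAN liver RNA with RNA of livers like chow replicates 1 and 2 is argued against. The 18 genes far higher in those replicates than in every GAN library allowed a median chow share of 4.10% (interquartile range 1.66% to 6.76%). In addition, 40 genes lay outside the range of all other libraries by 1.5 times. A trend with length or GC content is argued against as well. After its removal the correlation of chow replicate 3 with the GAN vector libraries still exceeded that with chow replicates 1 and 2 by 0.0194. A liver from a GAN-fed mouse under a chow label may be the source and stays open. Over 215 genes that separate chow replicates 1 and 2 (position 0) from the GAN libraries (position 1), the median position of chow replicate 3 was 0.965 (interquartile range 0.852 to 1.11), with 211 genes on the GAN side. These genes were picked by chow replicates 1 and 2, which lay close together. Genes peculiar to those replicates enter such a set and push any other library towards position 1. The position therefore cannot tell a GAN-fed liver from a chow-fed liver unlike chow replicates 1 and 2. A chow-fed mouse unlike the others stays open as well and was not tested. Lyz2 in chow replicate 3 was at 101 CPM, the level of the other chow livers and not the 215 CPM of GAN vector. Lyz2 was named by its small adjusted p in a fit with chow replicate 3. That choice favours genes on which the chow livers agree, so its level cannot weigh between the explanations.

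Clock genes differed between sIL1RAP and GAN vector in a pattern of phase. Of 18 genes grouped by the time of day at which they are known to peak, 17 passed the threshold, and 16 of these (94.1%) moved as a single shift of phase needs, Lonrf3 being the exception at 3.06-fold lower. A trend with length or GC content is argued against, since 100% of the 16 clock list members past the threshold stayed past it in their direction after its removal. A difference in time of day or feeding state between the groups when livers were taken is a candidate explanation, and these times are not given in the sources used here. An effect of sIL1RAP on the clock itself stays open too, and no value here separates it from such a difference. Whether a difference in time of day or feeding state also reached genes outside the clock list, Fgf21, Pdk4 and Lpin1 among them, was not tested.

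Genes of large ducts and mucosa were higher in the sIL1RAP libraries (7 of 10 genes of a mucosa list rose, 0 fell, median log2 fold change 2.28). An increase of the small ducts inside the liver large enough to lift their whole list is argued against. The small duct list had a median log2 fold change of -0.105, with 2 of 10 genes risen and 4 fallen, among them Sox9 at -0.91 and Spp1 at -0.57. Spp1 is also on the list of lipid-associated macrophage markers. The small duct genes were not split by their level in liver, so a smaller increase is not excluded. Pieces of gallbladder or large bile duct wall could bring both mucosa and smooth muscle, and the smooth muscle list had a median of 0.204 (interquartile range -0.41 to 0.92), which met the bound set against this explanation. That bound was wrong for genes with a high level in liver, where a small piece would not show: the 6 members under 3 CPM in chow, a level that does not enter the fold, had a median of 1.13 (interquartile range 0.12 to 1.88) and the 6 at or above 3 CPM a median of -0.10. Such pieces therefore cannot be told apart from a change of the ducts under sIL1RAP, because the members near the floor are few and both would follow the groups. Of 12 smooth muscle genes 4 rose and 3 fell. Ctrb1, a pancreas list gene chosen after its values were seen, had 156 reads in sIL1RAP against 0 in GAN vector. It was 40.8-fold higher against the floor of 3 reads (exact 95% lower limit 32.8). Only 2 of 15 pancreas genes were tested, so pancreas tissue was not tested as a set.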
